A study of Cucumis melo with 4 samples.

How the data were processed

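The series measured messenger RNA by Illumina sequencing in 2 cultivars of muskmelon (Cucumis melo), named BXC and YL in the labels, each with a control library and a salt-stressed library. The labels give 4 samples in 4 groups, with 1 sample per group, so no group has a replicate. Per the labels' protocols, plants grew in a greenhouse at 28 °C by day and 24 °C by night under a 14 h photoperiod. The sodium chloride given to the stressed plants was raised by 75 mM a day, to final levels of 150 and 300 mM. Which final level each stressed sample reached, and which tissue was taken, are not given in the sources used here. CASAVA and TopHat2 are named in the submitters' processing notes, without versions. The quantification tool is not given in the sources used here, and neither is the genome build, apart from locus names in the tables that begin with CM3.5.

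From each of the 2 deposited tables, a fold column and the columns of its test were used. The fold is the log2 fold between a table's 2 libraries, which the authors computed as second library over first, per the file headers. A placeholder in that column stands for an infinite fold, where a locus is listed at 0 in one of the libraries. The authors' p-value and q-value are for the same comparison. Recomputing the Benjamini-Hochberg adjustment over the loci whose status is OK returned the deposited q-value within 0.0001 for each of them in both tables. How the authors' test estimated variability from 1 library per group is not recorded. A deposited q-value is therefore reported as the authors' value, and it does not measure the spread between plants.

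The tables also hold 4 columns of per-library values, which were not used. Their headings number the libraries and carry no sample title or condition, so a column could be tied to control or salt only by its order, and order was not taken as evidence. For this reason every direction is given as second library over first, and the direction relative to salt is left open. The tables are told apart by the letters B and Y, which also begin the sample titles of BXC and YL. The numbers of the libraries run on from B to Y, and taken in the order of the labels they would give the same cultivars. Apart from that order, the letter is the only tie between a table and a cultivar. The comparison of the cultivars without salt needs a mapped control column and was not made. The comparisons fixed before the data were examined assumed mapped per-library RPKM values, with an RPKM minimum and a pseudocount. The deposited folds replaced them, so neither was applied here. The 2-fold and 4-fold limits on the counts of each table had been fixed beforehand. A difference of the salt responses gene by gene had been fixed too and was not computed, since it needs the treatment order of both tables. The use of the authors' q-value with a limit of 0.05, the kinds of locus, the correlation and overlap between the tables and the bootstrap were chosen after the data were seen.

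Both tables list the same 32625 loci in the same order. They hold 27427 distinct MELO3C identifiers, some of them listed at more than 1 locus, and no gene names or functions. None of these identifiers occurs in the reference table supplied, which covers 28628 genes of the USDA_Cmelo_AY assembly, so 0 of 27427 matched. The 37 gene lists fixed before the data were examined (pathways, transcription factor families, tissue markers) could therefore not be filled, and the naming rule (the most changed annotated genes per cultivar above an RPKM minimum) could not be applied. Loci were grouped by what the tables themselves say: 1 identifier, several identifiers, or no identifier (called unannotated here), and by whether they lie on a scaffold or an unplaced contig. The 4 loci named in the text were chosen after their values were seen. They are the 2 highest and the 2 lowest mean log2 folds among loci with 1 identifier, a region of their own, and a deposited q-value under 0.05 in both tables. Coordinates are those of the tables, converted to count from 1, since 207 regions start at 0. A region can span more than the gene itself: 5753 loci share their exact region with another locus.

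Folds were summarised over loci with status OK and a finite fold. The numbers at least 2-fold higher or lower describe these libraries and carry no p-value. Intervals are 95% percentile intervals from 1000 bootstrap draws of whole scaffolds and contigs. They cover the spread over loci, not between plants, and loci are not independent replicates. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures used matplotlib 3.10.9. The procedures were tested on simulated data for the 15552 loci with a fold in both tables. A simulated correlation of 0.5 came back as 0.513. All 200 loci changed 4-fold were counted at the 2-fold limit, as were 0.13% of unchanged loci. The simulated folds of unchanged loci were spread far more narrowly than the deposited folds. These shares therefore check the counting alone and give no error rate for the counts below. A scan for stretches of 10 neighbouring loci found 18 of 20 simulated stretches raised by 3 on the log2 scale among 10395 loci. Lowered stretches were not simulated, so this gives no detection rate for the lowest window. Alternatives were the 4-fold limit and, added after seeing the data, centring on each table's median, other sets of loci, other q limits and a rank correlation. The columns used give no read counts, so the depth behind each fold is unknown and no counting interval is given.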

Results

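Transcript levels were compared between salt-stressed and control plants of 2 muskmelon cultivars, BXC and YL, with 1 library for each of the 4 combinations. The deposited data are 2 tables, B and Y, each comparing 2 libraries over 32625 loci. Their letters are those that begin the BXC and YL sample titles. The columns do not say which library of a pair was salt-stressed, so each fold is the authors' log2 of the second library over the first. No difference below has a replicate check. The loci carry MELO3C identifiers without gene names, and the depth behind each fold is unknown. Of these loci, 27744 carry 1 identifier, 955 carry several, and 3926 carry none.

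The B table, by its letter, addresses the response of BXC to salt. Of 16008 loci with a finite fold, 3523 were at least 2-fold higher in the second library and 4201 were at least 2-fold lower, together 48.3%. At 4-fold the counts were 1637 higher and 1796 lower. The median log2 fold was -0.14 (95% interval over scaffolds -0.17 to -0.10), with quartiles of -1.06 and 0.84. Relative to that median, 3951 loci were at least 2-fold higher and 3728 lower, and centring of itself brings the sides close to balance. In the authors' deposited table, 37 loci were higher and 36 lower at a q-value under 0.05. Of these, 64 carry 1 identifier, 8 are unannotated and 1 carries several identifiers. The smallest change called in the authors' deposited table was 41.4-fold. The authors' unadjusted p-value was under 0.05 for 1166 of the 17607 tested loci. If the p-values are well calibrated, a share of 0.05 would pass that limit without any change.

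The Y table addresses the response of YL in the same way. Of 19009 loci with a finite fold, 4500 were at least 2-fold higher in the second library and 6145 were at least 2-fold lower, together 56.0%. At 4-fold, 2671 were higher and 3188 lower. The median log2 fold was -0.29 (95% interval -0.34 to -0.24), with quartiles of -1.37 and 0.89. Relative to that median, 5305 loci were higher and 5029 lower, near balance by construction as in B. Without centring, the larger side changed when the loci listed at 0 in one library were counted, with 7132 higher and 6630 lower. In the authors' deposited table, 41 loci were higher and 73 lower at a q-value under 0.05. These were 96 loci with 1 identifier and 18 unannotated loci. The smallest change called in the authors' deposited table was 55.5-fold. The authors' unadjusted p-value was under 0.05 for 1485 of the 22126 tested loci, to be read against the same share as in B.

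The 3 kinds of locus did not all move alike, although in Y the intervals of loci with 1 and with several identifiers overlapped. Loci with 1 identifier had a median log2 fold of -0.14 in the B table (95% interval -0.17 to -0.10, 13509 loci) and -0.38 in the Y table (-0.41 to -0.32, 15667 loci). Loci with several identifiers, whose annotated genes share 1 value, lay at -0.37 in B (-0.44 to -0.29, 916 loci) and -0.42 in Y (-0.50 to -0.35, 942 loci). Among finite folds, unannotated loci lay at 0.04 in B (-0.04 to 0.13, 1583 loci) and at 0.60 in Y (0.50 to 0.73, 2400 loci). With loci listed at 0 in one library counted, unannotated loci leaned to the second library in both tables: 58.7% of 2120 tested were higher there in B (56.5 to 61.0) and 72.5% of 3761 in Y (70.8 to 74.2). Among finite folds alone the shares were 51.0% in B and 60.3% in Y. Of all tested loci with 1 identifier, 47.2% were higher in B and 43.6% in Y. Among Y folds, 43.2% of unannotated loci were at least 2-fold higher in the second library and 23.8% at least 2-fold lower. The corresponding shares of loci with 1 identifier were 21.3% and 33.7%. Unannotated loci on scaffolds had a Y median of 0.75 (0.59 to 0.86, 1817 loci), and those on unplaced contigs one of 0.25 (-0.01 to 0.44, 583 loci). In B these medians were 0.07 on scaffolds (-0.03 to 0.16) and -0.03 on contigs (-0.18 to 0.14). Loci with 1 identifier on contigs had medians of -0.40 in B (-0.60 to -0.18, 268 loci) and -0.99 in Y (-1.15 to -0.80, 298 loci), below those on scaffolds, at -0.14 and -0.37. The set of tested loci differed too: 54.0% of unannotated loci had status OK in B and 95.8% in Y, against 52.5% and 62.8% of loci with 1 identifier. Among unannotated loci with a fold in both tables, the Y median was 0.05.

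**Figure D1:**
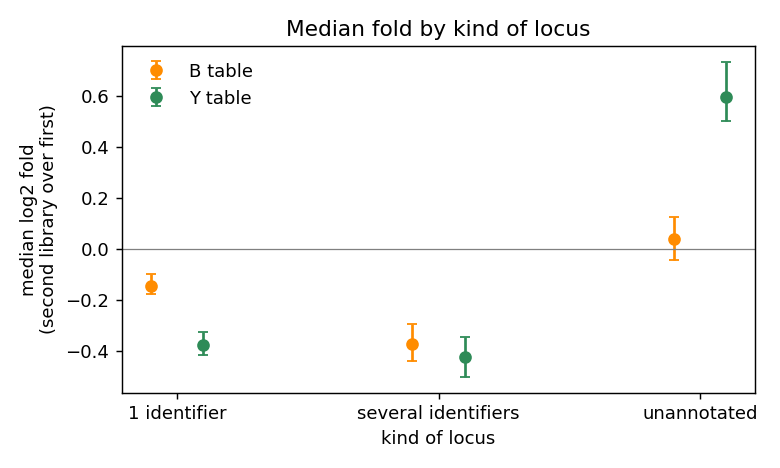
Median of the finite log2 folds of the second library over the first (vertical axis) for loci with 1 identifier, with several identifiers and without one, in the B and Y tables; points are medians and bars are 95% bootstrap intervals over scaffolds. The unannotated loci of the Y table lie at 0.60, above the other 5 medians, which lie between -0.42 and 0.04.

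The responses of the cultivars were compared over the 15552 loci with a finite fold in both tables. In both tables together, 12223 loci, 78.6% (95% interval 77.9 to 79.2), had the same direction. Across these loci Pearson's r was 0.770 (0.759 to 0.780) and Spearman's rho 0.746. These are correlations across genes, which are not independent replicates, and their sign holds for the library order as deposited. At 2-fold, 2007 loci were higher in the second library of both tables and 3173 lower in both. Independent lists would share 620 and 1328. Opposite changes of at least 2-fold were seen at 272 loci, against 1844 for independent lists. In B 47.6% of the shared loci differed at least 2-fold (46.9 to 48.4), and in Y 51.2% did (50.3 to 52.1). The gap was 3.58 percentage points (2.76 to 4.29), and it narrowed to 1.52 (0.777 to 2.35) when each table was centred on its median. With 1 library per group, a gap between cultivars cannot be separated from one between single libraries.

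**Figure D2:**
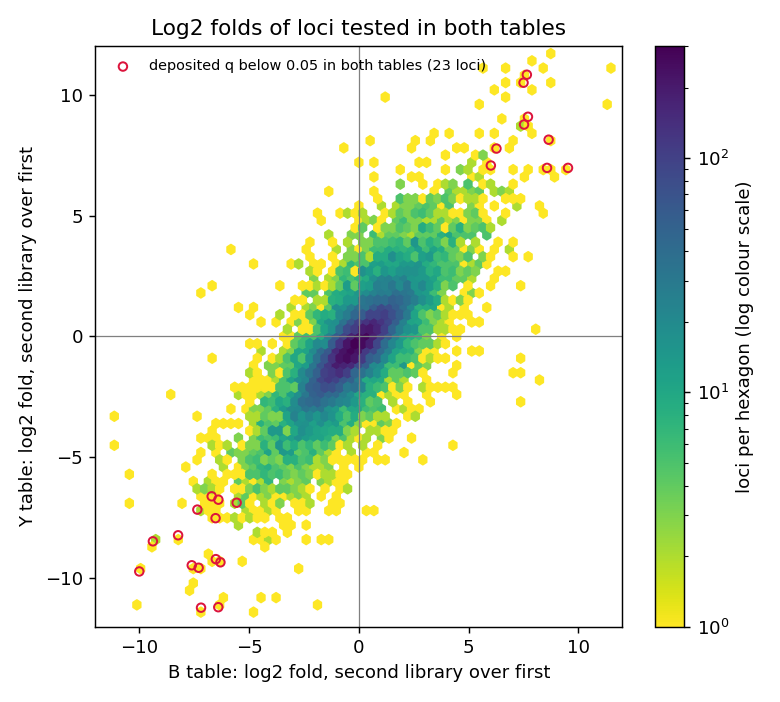
Log2 fold of the second library over the first in the B table (horizontal axis) against the Y table (vertical axis) for the loci with a finite fold in both; colour gives the number of loci per hexagon on a log scale, red circles mark the 23 loci with a deposited q-value under 0.05 in both tables, and 3 loci lie beyond the axes. The cloud follows the rising diagonal, and the circled loci sit in the upper right and lower left corners.

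The loci called in the authors' deposited tables mostly moved together where they had a finite fold in both. Of the 37 higher and 36 lower loci called in B, 33 and 33 had such folds. Of the 41 higher and 73 lower loci called in Y, 21 and 59 had them. The other called loci could not be compared in this way. Of the 66 loci called in B and the 80 called in Y that had a finite fold in both, 23 were called in both, 9 higher and 14 lower in the second library. Independent lists would share 0.0446 and 0.125 loci. Among loci at least 4-fold changed in either table, called or not, 91.1% shared a direction. The overlap of called loci is therefore no separate support beyond the correlation over all loci. Of the 43 loci called in B alone, 42 were at least 2-fold changed the same way in Y, as were all 57 of the loci called in Y alone when looked up in B. The 33 loci called higher in B had a median log2 of 7.02 there and 5.78 in Y. The 33 called lower in B had medians of -6.99 and -6.75. For the loci called in Y, the medians were 7.77 in Y and 6.01 in B among the higher ones, and -7.51 and -4.52 among the lower ones. Loci picked for large folds in one table tend to have smaller ones in the other by that choice alone. These pairs of medians therefore do not compare the size of the cultivars' responses. Of the 23 shared loci, 19 carry 1 identifier and 4 are unannotated.

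The most changed of the shared loci with 1 identifier were picked after their values were seen, from the authors' deposited tables. In the authors' deposited table, MELO3C007961 (CM3.5 scaffold00007, positions 6484764 to 6486134) was 201-fold higher in the second library of B, a log2 of 7.65 with a q-value of 0.00534, and 1816-fold higher in Y, a log2 of 10.83 with a q-value of 0.00572. MELO3C010323 (scaffold00012, 5982016 to 5984007) was 208-fold higher in B and 544-fold higher in Y, with log2 folds of 7.70 and 9.09 and q-values of 0.0260 and 0.0493 in the authors' deposited tables. MELO3C007153 (scaffold00007, 1145930 to 1147062) was 1027-fold lower in B and 842-fold lower in Y, with log2 folds of -10.00 and -9.72 and q-values of 0.00141 and 0.0150 in the authors' deposited tables. MELO3C014627 (scaffold00022, 4563868 to 4570590) was 146-fold lower in B and 2378-fold lower in Y, with log2 folds of -7.19 and -11.22 and q-values of 0.00810 and 0.00235 in the authors' deposited tables. The tables give no function, exon or UTR for these loci. Their per-library values were not used, so whether these folds rest on low levels was not assessed.

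Some tested loci were listed at 0 in one library, and no fold is given for them. In B there were 1098 such loci with 0 in the first library and 501 with 0 in the second. In Y there were 2632 and 485. None of them had a q-value under 0.05 in the authors' deposited tables. Unannotated loci made up 438 of the 1098 at 0 in the first library of B and 99 of the 501 at 0 in its second. In Y they made up 1281 of the 2632 and 80 of the 485. Those tested in both tables mostly kept their direction. Of loci with a finite fold in both tables, 78.6% did so. The share for loci at 0 in the second library of B, 76.5%, was no higher than that. Of 1012 loci at 0 in the first library of B, 92.0% were higher in the second library of Y, and of 400 at 0 in the second library of B, 76.5% were lower in the second library of Y. Of 817 loci at 0 in the first library of Y, 88.9% were higher in the second library of B, and of 191 at 0 in its second library, 87.4% were lower.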

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

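At some loci the tables went in opposite directions, and with 1 library per group these differences were not tested. At 4-fold, 37 loci were changed in opposite directions, 20 higher in B and lower in Y and 17 the reverse, while 890 were higher in both and 1284 lower in both. Of the 123 loci with a fold in both tables and a q-value under 0.05 in at least one of the authors' deposited tables, 122 had the same direction in both. The exception, singled out after its values were seen, is a locus with 1 identifier on CM3.5 scaffold00001, positions 4557244 to 4560236. In the authors' deposited tables its log2 fold was -6.61 in B, with a q-value of 0.020, and 2.05 in Y, with a q-value of 0.724.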

How the results depend on the processing

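The 4-fold limit on the counts of each table was fixed before the data were examined, and the other alternatives were chosen after seeing the data. Other pseudocounts, RPKM minimums, scalings of the libraries and a minimum of reads per gene had been fixed too and were not run. They need read counts or the per-library values, which were left unused. A pseudocount, an RPKM minimum or a scaling within a table would not need the treatment of each library. The folds and counts given here therefore have no expression floor. No paired analysis of salt against control was possible because the columns do not give the treatment of each library. A test of second over first libraries with the cultivars as pairs was not run. Of 82 alternative values over 16 results, 52 stayed the same by the limits set (counts within 1.5 times, others within their 95% interval), 29 moved and 1 reversed. A count could not be labelled reversed, and each side was labelled on its own. Centring turned the larger side, to 3951 higher and 3728 lower in B and 5305 and 5029 in Y, yet these counts are labelled the same. Counts over fewer loci also shrink by that choice. The tally is therefore no measure of how stable the balance of higher and lower loci was. At 4-fold, the counts fell to 1637 higher and 1796 lower in B, 2671 and 3188 in Y, and 37 opposite loci, and the gap between Y and B in the share of changed loci was 5.03 percentage points. Among loci at least 4-fold changed in either table, a set chosen for large folds, r was 0.804 and 91.1% shared a direction. Centring narrowed the 2-fold gap between Y and B to 1.52 percentage points. At a q-value under 0.01 the deposited tables hold 9 higher and 8 lower loci in B and 13 and 15 in Y, and under 0.1 they hold 89 and 82 in B and 85 and 166 in Y. With loci listed at 0 counted, the balance in Y turned, to 7132 loci at least 2-fold higher and 6630 lower, while B kept more lower loci (4621 higher, 4702 lower). The correlation was 0.783 without shared regions, 0.782 for loci with 1 identifier, 0.746 as a rank correlation, and 0.719 over finite folds of any status, where 76.7% shared a direction. The causes of these shifts in r were not tested. The B median of unannotated loci reversed from 0.04 to -0.0024 among loci tested in both tables, both within its interval around 0. In Y it fell from 0.60 to 0.41 without shared regions and to 0.05 among loci tested in both tables, and was 0.75 on scaffolds. The per-library values could show how many of these folds lie at low levels, but they were not used. The read depth is unknown. How far low levels or low counts widen the folds was therefore not assessed.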

Other observations

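Of the tests below, those on locus length were set before their values were seen. The others, with their limits, were chosen after related values had been seen.

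Neighbouring loci tended to change together. Where the regions of successive tested loci overlapped, their log2 folds correlated at r = 0.340 in B (95% interval 0.265 to 0.398, 1279 pairs) and 0.362 in Y (0.323 to 0.401, 2006 pairs). Separate neighbours less than 2000 bp apart reached 0.125 (0.0931 to 0.157) and 0.170 (0.132 to 0.207), and those over 20000 bp apart 0.0427 and 0.0561. The overlapping pairs lie above the separate ones in both tables with intervals apart. Reads or transcript pieces shared by loci with overlapping regions may account for that excess. Common regulation of overlapping genes was not tested and stays open. Whether stretches of 10 loci change together depended on how the limit was set. Among 9050 windows the lowest mean over both tables was -2.75, on CM3.5 scaffold00014 from 1312625 to 1387441, with each log2 fold limited to a size of 5. It passed the limit of -2.74 first used, the 5th percentile of the lowest window in 1000 shuffles, by a margin in the third decimal. After that was seen, the limit was changed to cover both ends of the scan together, and the window lies inside the resulting limit of -2.83. The highest window, at 1.85, lies inside both limits (1-end 2.14, both ends 2.24). The window is therefore left open, and shorter or weaker stretches would be missed.

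Unannotated loci leaned to the second library: 58.7% of those tested were higher there in B and 72.5% in Y. In B the lean came from loci listed at 0, 438 in the first library against 99 in the second, since 51.0% of finite folds were higher. In Y, 60.3% of finite folds were higher. The tests below are on the Y table. The short length of unannotated loci does not account for the whole of this. At matched length and outside shared regions, 22.6 percentage points more of them than of loci with 1 identifier were higher in the second library (95% interval 20.2 to 25.1, against 31.7 unmatched). Over the 5 length classes, however, the gap was uneven, as low as 6.02 points in 1 class and as high as 32.7 in another. Unplaced contigs are not the whole source, since the median of unannotated loci on scaffolds was 0.75. Whether foreign sequence adds to the lean on contigs was left undecided. The median on contigs was lower, at 0.25, with intervals apart. Loci with 1 identifier were lower on contigs too, at -0.99 against -0.37 on scaffolds, so that gap is not particular to unannotated loci. Whether unannotated loci were defined mainly from reads of the Y table's second library was also left undecided. Of 1740 unannotated loci tested in Y alone, 86.5% were higher in that library (84.7 to 88.3; 941 of them were listed at 0 in the first), 26.0 points more than of the 2021 tested in both tables (60.5%, 58.0 to 63.0). Loci with 1 identifier showed a step in the same direction, from 39.8% of 14316 tested in both to 60.7% of 3100 tested in Y alone. Being tested in Y alone depends on the reads of the Y libraries themselves, so this comparison gives no support to that explanation. Transcription that salt changes was not tested and stays open.

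The parallel folds of the tables were not explained by a trend with locus length shared by the tables. Within 5 classes of length the lowest correlation was 0.725 (95% interval 0.694 to 0.753), in the longest loci, against 0.770 pooled. With 1 library per group, and no column that gives a library's treatment, whether the shared direction follows salt was not tested.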
